A study of Mus musculus with 12 samples.

How the data were processed

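Total RNA of mouse submandibular gland was measured on 12 Illumina bead arrays, 6 from C57BL6J mice of 8 weeks and 6 from mice of 50 weeks. Per the labels, RNA was extracted with Trizol, cleaned and treated with DNase I on RNeasy columns, checked on a Bioanalyser and labelled as biotinylated cRNA with the Ambion MessageAmp kit. The deposited table holds a probe intensity on the linear scale for 45281 probes and 12 arrays, with no stated scaling between arrays. Per the file headers, each intensity column is followed by a detection p-value for the same array. A second deposited table, the series matrix, holds the same intensity values, which the authors multiplied by 1 factor per array (0.803 to 1.26). Every array of that table therefore had a mean of 260.6, while its medians ran from 93.6 to 121. The matrix values were linear, were not centred by probe, and higher values stood for more signal. The scanner, summary software, slide positions, sex of the mice and time of dissection are not given in the sources used here. The titles number the mice within each age, but nothing states that each array is a separate animal. The p-values therefore measure the spread between these samples, which may be technical in part.

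Intensities were background-corrected and quantile-normalised with neqc of limma 3.58.1 in R 4.3.3, with the background taken from the detection p-values, an offset of 16 and log2 values throughout. The package data.table, version 1.17.8, handled the tables, and array weights used statmod 1.5.0. A probe was kept when its detection p-value was under 0.05 on at least 6 of the 12 arrays, which left 16254 probes. Probe symbols came from the annotation table of the array, where 34885 probes had 1 symbol, 18 had several and 10378 had none. Of these, 34807 were matched by gene number to the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. The assembly served for names only, and no positions are given. Among the 13842 kept probes with 1 symbol, the probe with the highest mean log2 intensity stood for its gene, which gave 9379 genes.

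The 50-week arrays were compared with the 8-week arrays by limma's moderated test (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A log2 change of at least 1 counted as at least 2-fold. All changes are log2 values at 50 weeks minus those at 8 weeks, with the standard error of the fit, and group values are means ± SD of 6 arrays. The floor of an array was the log2 intensity of its lowest detected probe, with a mean of 5.02 at 8 weeks and 4.92 at 50 weeks. For a named gene whose mean in a group lay below that floor, or that was detected on at most 3 of its 6 arrays, the fold is given as a bound, with each value below the floor of its array raised to it.

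Gene lists for cell types, secretory products and pathways, 33 in number, were written from general knowledge, and 0 measured genes stood in more than 1 list. Each list with at least 3 measured members was tested on its mean log2 intensity per array, by a 2-sided exact permutation test over every arrangement of the 12 arrays. The smallest p it can give is 0.00216, and values were adjusted by Benjamini-Hochberg over the 30 lists tested. With a covariate, the list means and each arrangement of the ages were first adjusted for it. Permutation p values with a covariate are therefore approximate and not exact. Lists were also tested with camera of limma, which compares a list with all other genes, with a preset correlation of 0.01 between genes and with an estimated correlation. With the preset correlation 14 lists passed, and with the estimated correlation 1 list passed, that of myoepithelium and smooth muscle. For each list the number of changed members is given over all genes tested and adjusted over the list alone.

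Named genes are the 12 largest rises and 12 largest falls among genes past the threshold, leaving out predicted or clone names (1 among the rises, 2 among the falls), and up to 4 members of each list with the smallest adjusted p. The lists, this rule, the tests and most of the alternatives were chosen before the data were examined. A gene outside the rule is given as chosen after its values were seen. Correlations between genes over the 12 arrays were taken after removing the mean of each age, with 100000 permutations of arrays within each age. Bootstrap intervals of 95% came from 10000 draws of arrays, with replacement, within each age.

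The gene and list tests were tried on simulated log2 values of 9379 genes with 6 arrays a group. Each gene was drawn independently of the others, and the background, scaling, filter and probe steps were not simulated. The test recovered 54.5% of the genes with a log2 change of 0.5, 91% at 1 and 100% at 2, with 10 false among 174 calls. All 5 simulated lists that moved were found, and 1 of 15 that did not move was called. Members of real lists can vary together between arrays, so these list counts may not carry over to them. Alternatives changed the background step, the offset, the scaling between arrays, the detection filter, the choice of probe, the test, array weights, a replicate block and the arrays included. The authors' matrix values were used as another alternative. The number of arrays limits the precision. Nothing in the deposited tables was left out of the comparison except probes below the filter, probes without a single symbol and the dimmer probes of genes with several.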

Results

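Gene expression was measured in the submandibular salivary gland of C57BL6J mice at 8 weeks and 50 weeks, with 6 arrays per age. The question was what differs between these ages, called young and old below. With these ages only, maturation after 8 weeks and later ageing cannot be told apart. Mean probe intensity ran from 207 (8 weeks array 5) to 324 (8 weeks array 1), and the 50-week arrays lay between 223 and 302. Probes detected ran from 15318 on 50 weeks array 6 to 18110 on 50 weeks array 3. The first principal component held 28.5% of the variance and separated the ages (exact permutation p = 0.00216, the smallest possible). The second component held 25.6%, did not separate the ages (exact permutation p = 1), and had its highest value, 45.1, on 50 weeks array 6. That array correlated with the others of its age at a mean r of 0.949, against 0.979 or more for each of the rest.

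**Figure D1:**
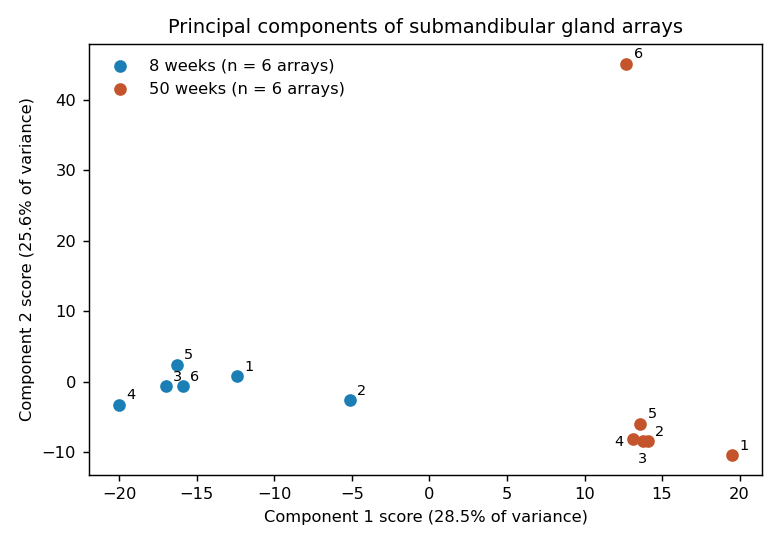
Each point is 1 of the 12 arrays, placed by its first and second principal components of log2 intensity (axes in component units), coloured by age. The 50-week arrays lie to the right of the 8-week arrays on the first axis, and 50 weeks array 6 lies apart on the second axis at 45.1.

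Of 9379 genes tested, 1171 (12.5%) differed between the ages: 596 were higher at 50 weeks and 575 were lower. At least 2-fold changes were mostly rises, with 75 genes higher and 22 lower among 97. The median size of a change was 0.47 on the log2 scale. In 542 of the changed genes the values of the 6 old and 6 young arrays did not overlap. Over all genes 605 did not overlap, where chance gives 0.216%. Without 50 weeks array 6 the count of changed genes was 2317, with 1047 higher and 1270 lower, and without 50 weeks array 1 the count of lower genes was 380. Scaling each array to the same median in place of the quantile step gave 393 changed genes, 320 higher and 73 lower, and moved the median change of all genes by 0.121.

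The highest fitted log2 change was that of Ptgds, the lipocalin-type prostaglandin D synthase (probe ILMN_1248316), from 5.32 ± 0.45 to 8.45 ± 0.25 (SD, n = 6), an 8.79-fold rise (log2 change 3.14 ± 0.19, adjusted p = 3.87e-07). Mzb1, a chaperone of plasma cells and B cells, was detected on 2 of 6 young arrays and was at least 6.87-fold higher (2.97 ± 0.34, adjusted p = 0.000128). Slpi, a secreted protease inhibitor, was detected on 0 of 6 young and 6 of 6 old arrays and was at least 4.78-fold higher, and Amtn, the enamel-associated protein amelotin, was at least 3.34-fold higher with the same detection. St6galnac1, a sialyltransferase that acts on mucin-type glycans, was detected on 3 of 6 young arrays and was at least 4.56-fold higher (2.27 ± 0.16). Of the chemokine genes, Ccl5 rose by 1.82 ± 0.37. Ccl8, detected on 2 of 6 young arrays, was at least 5.71-fold higher (2.78 ± 0.45), and Cxcl9, detected on 1 of 6, was at least 3.96-fold higher (2.27 ± 0.25). Gbp2, an interferon-induced GTPase, rose by 1.93, and Cd209f, a C-type lectin, by 1.80, while Tac1, the precursor of substance P, detected on 3 of 6 young arrays, was at least 2.92-fold higher. C2cd4a, detected on 1 of 6 young arrays, was at least 5.86-fold higher on its brightest probe and rose by 0.73 on another. Of these 12 genes, Gbp2 and Ccl5 were above every young array on 5 of 6 old arrays, and the other 10 on 6 of 6.

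The lowest fitted log2 change was that of Sult1e1, the estrogen sulfotransferase (probe ILMN_1216300), from 7.57 ± 0.83 to 4.82 ± 0.30 (SD, n = 6); it was detected on 2 of 6 old arrays and was at least 6.04-fold lower at 50 weeks (log2 change -2.75 ± 0.31, adjusted p = 0.000128). Dbp, a transcription factor driven by the circadian clock, changed by -1.70 ± 0.27 and Ly6d, a cell-surface protein, by -1.54 ± 0.11 (adjusted p = 1.72e-06). Insig1, a regulator of sterol synthesis, changed by -1.35 ± 0.25, Pdk4, a kinase that inhibits pyruvate dehydrogenase, by -1.33 ± 0.17, and Hsd11b1, which regenerates active glucocorticoid, by -1.28 ± 0.18 (-0.74 on another probe). Ttr, the thyroid hormone carrier transthyretin, changed by -1.31 ± 0.19, and Col4a5, a basement membrane collagen, by -1.16 ± 0.10 (-0.55 on another probe). Ddit4l, Pcsk6 and Chst7 changed by -1.27, -1.26 and -1.16, and the receptor subunit Chrna4, detected on 0 of 6 old arrays, was at least 1.93-fold lower. All 12 of these genes were below every young array on 6 of 6 old arrays. Without background correction the changes of 48 of the 94 named genes past the threshold were smaller by over 1.5 times, with 1.77 for Ptgds and -1.32 for Sult1e1, and 0 changed sign.

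**Figure D2:**
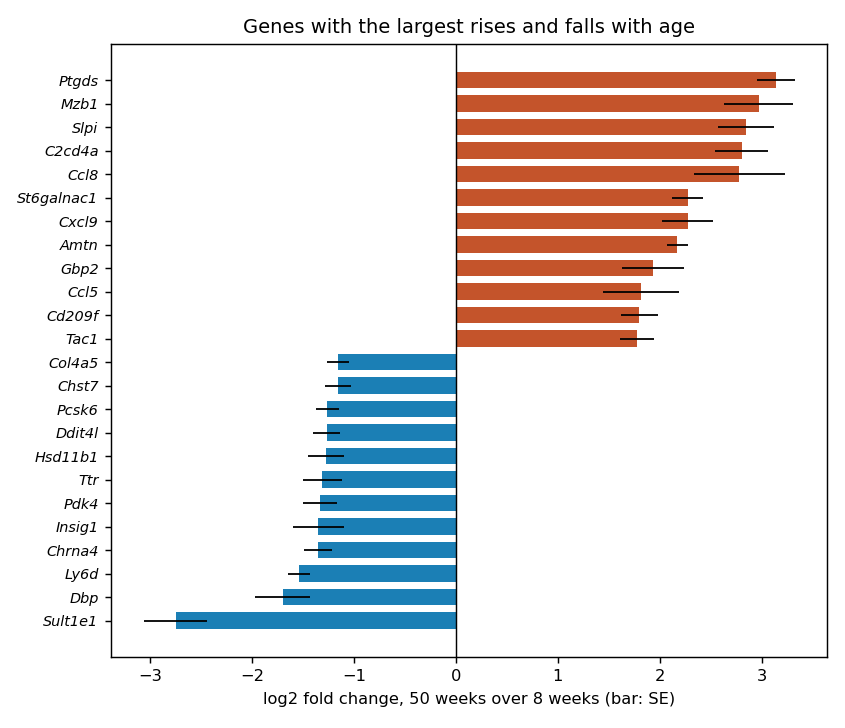
Bars give the fitted log2 fold change of 50 weeks over 8 weeks for the genes with the 12 highest and the 12 lowest values, with the standard error of the fit as whiskers (6 arrays per age). Ptgds has the highest fitted value, 3.14, and Sult1e1 the lowest, -2.75; the genes Mzb1, Slpi, C2cd4a, Ccl8, St6galnac1, Cxcl9, Amtn, Tac1, Sult1e1 and Chrna4 were detected on at most 3 of 6 arrays at 1 age, so their folds are bounds and their order is not determined.

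Gene lists written for cell types and pathways were compared by their mean on each array. Of 30 lists tested, 11 were higher and 6 lower at 50 weeks. With each array scaled to the same median, 0 lists passed. Relative to the median change of all genes in that setting, 0.103, the 17 lists kept their sign. Taking out that median largely puts back the centring of the quantile step, so the kept signs are weak evidence. Without 50 weeks array 1, 0 lists passed (lowest adjusted exact permutation p = 0.0531), without 8 weeks array 5, 10 passed, and without 8 weeks array 6, 11 passed. Of the 6 lower lists, 2 passed without 8 weeks array 5 or 6, 3 without 50 weeks array 2, 3 or 4, and 1 on the authors' values. Without both 8 weeks array 2 and 50 weeks array 6, 3 lists were lower, among them oxidative phosphorylation, which is not 1 of the 6. With Amy1 as a covariate 2 lists were lower, among them granular duct secretory products, also not 1 of the 6. That covariate ended the calls of duct epithelium, collagens, antioxidant enzymes, the clock, the sex-linked list and, among higher lists, nerve and Schwann cells. Their adjusted approximate permutation p ran from 0.0609 to 0.0812.

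**Figure D3:**
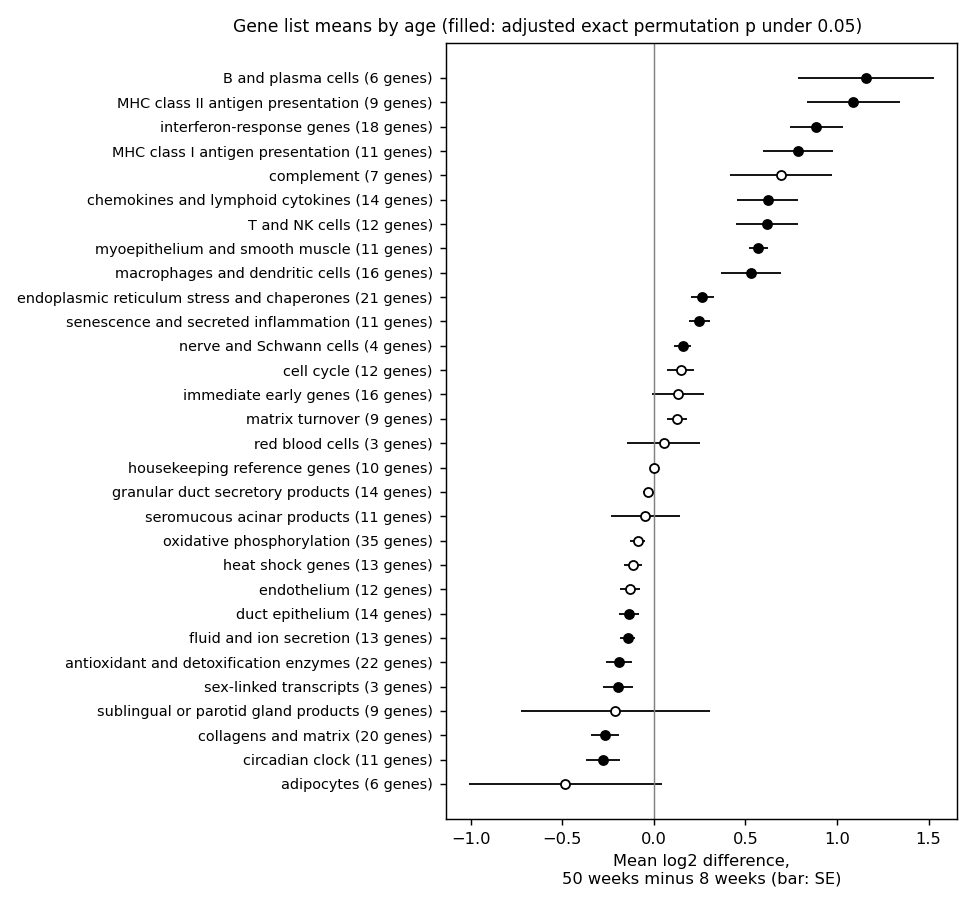
Points give the difference in mean log2 intensity, 50 weeks minus 8 weeks, of each of 30 gene lists, with its standard error as bars (6 arrays per age), filled where the adjusted exact permutation p passed. B and plasma cells lie highest at 1.16, and of the filled lists the circadian clock lies lowest at -0.28; with each array scaled to the same median no list passed.

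Antigen presentation was higher at 50 weeks. The list of MHC class II genes, which present peptides to helper T cells, rose from 7.61 ± 0.58 to 8.70 ± 0.23 (SD, n = 6), a difference of 1.09 ± 0.25 (adjusted exact permutation p = 0.0325; adjusted p = 0.269 with an estimated correlation). Of its 9 measured members 7 rose, 9 when adjusted over the list alone, among them H2-Eb1 (1.62 ± 0.27), H2-Ab1 (1.42 ± 0.26) and H2-DMa (1.11 ± 0.22). The MHC class I list differed by 0.79 ± 0.19 (adjusted exact permutation p = 0.0325; adjusted p = 0.269 with an estimated correlation). In it 9 of 11 members rose, 11 adjusted over the list alone, including the immunoproteasome subunit Psmb9 (1.44 ± 0.25), the peptide transporter Tap1 (1.15 ± 0.21) and the light chain B2m (0.87 ± 0.21). Each list was above every young array on 3 of 6 old arrays. Both were higher on 8 weeks array 2 than on the other young arrays, with 8.66 against at most 7.90 for class II and 9.25 against at most 8.46 for class I. Without 50 weeks array 1 the adjusted exact permutation p of each was 0.0531.

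Interferon-response genes and chemokines were also higher as lists. The interferon list rose by 0.89 ± 0.14, from 6.95 ± 0.29 to 7.84 ± 0.20 (SD, n = 6), above every young array on 6 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.203 with an estimated correlation). Of 18 members 14 rose, 17 adjusted over the list alone, with Cxcl9 at least 3.96-fold higher, Ifi47 at 1.42 ± 0.20 and Ifit3 at 0.97 ± 0.14. Cxcl10 was detected on 0 of 6 young arrays and was at least 1.12-fold higher, with adjusted p = 0.166 on the authors' values. The chemokine list rose by 0.62 ± 0.17 (adjusted exact permutation p = 0.0325; adjusted p = 0.298 with an estimated correlation). Of its 14 members 6 rose, and adjusted over the list alone 8 rose and 1 fell. These included Ccl8, Ccl7 (at least 1.66-fold higher), the stromal chemokine Cxcl12 (0.60 ± 0.11) and the B-cell survival factor Tnfsf13b (0.85 ± 0.16). The list differences were 0.50 for interferon and 0.29 for chemokines without background correction and 0.51 and 0.30 on the authors' values, and the strict detection filter left 0.34 for chemokines (adjusted exact permutation p = 0.0902). Leaving out 50 weeks array 1 gave 0.0531 for the interferon list, and leaving out 50 weeks array 1, 2 or 5 ended the chemokine call, at up to 0.0693. The interferon list stood at 7.52 on 8 weeks array 2, against at most 6.97 on the other young arrays, and the chemokine list at 6.85 and 6.90 on 8 weeks arrays 1 and 2, against at most 6.20.

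Lists of lymphocyte and myeloid cell transcripts moved the same way. The B and plasma cell list rose by 1.16 ± 0.37, above every young array on 4 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.298 with an estimated correlation). Of 6 members measured, of 14 on the array, 3 rose, 4 adjusted over the list alone: Mzb1, Pou2af1, a transcriptional coactivator of B cells (at least 2.26-fold higher, detected on 1 of 6 young arrays), and Fcrla (at least 1.46-fold higher, detected on 2 of 6), which lost its call without 8 weeks array 4 or 50 weeks array 1 (adjusted p up to 0.166). Cd79b, a chain of the B-cell receptor detected on 2 of 6 young arrays, had a fold bound of 1.57 (fitted difference 1.06 ± 0.44). It did not pass (adjusted p = 0.136), but passed without 8 weeks array 1 (fitted difference 1.36, adjusted p = 0.0383). The T and NK cell list rose by 0.62 ± 0.17, above every young array on 5 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.269 with an estimated correlation). In it 5 of 12 members measured, of 21 on the array, rose, 9 adjusted over the list alone, among them the T-cell receptor subunit Cd3g (at least 1.92-fold higher, detected on 2 of 6 young arrays) and the granule protein gene Nkg7 (1.34 ± 0.30). The list of macrophages and dendritic cells rose by 0.53 ± 0.17, above every young array on 1 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.298 with an estimated correlation). Of 16 members 8 rose, and adjusted over the list alone 13 rose and 1 fell. Aif1 rose by 0.96 ± 0.22, Mpeg1 by 0.91 ± 0.21 and C1qc by 0.81 ± 0.20. The T and NK list members Cd247, Cd8a and Gzmb were detected on 0 of 6 arrays of each age. So were Tnfrsf17, Cr2 and Pax5 of the B and plasma cell list, while Jchain was detected on 0 of 6 young and 3 of 6 old arrays. Members below the filter did not enter the list means. Among young arrays, 8 weeks arrays 1 and 2 stood highest, with 5.96 and 5.74 for B and plasma cells against at most 4.76, 6.28 and 6.41 for T and NK cells against at most 5.69, and 8.03 and 8.495 for macrophages against at most 7.67. The B and plasma cell and T and NK cell differences were 0.57 and 0.35 without the detection filter, 0.51 and 0.27 without background correction, and 0.50 and 0.24 on the authors' values, where the macrophage call ended (adjusted exact permutation p = 0.0595). Leaving out 50 weeks array 1 ended all 3 calls, with 0.0531 for T and NK cells. Leaving out 8 weeks array 3, 4, 5 or 6 ended those of B and plasma cells (up to 0.0667) and of macrophages (up to 0.0649, also without 50 weeks array 2 or 5).

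The complement list differed by 0.69 ± 0.28 and did not pass (adjusted exact permutation p = 0.068). Without 8 weeks array 2 it differed by 0.92 and passed (adjusted exact permutation p = 0.00897). It also passed with the adipocyte list as a covariate (adjusted approximate permutation p = 0.00928), and without the detection filter it differed by 0.43. Of 7 members 1 rose, 6 adjusted over the list alone. That member, C2, differed by 0.89 ± 0.24 (adjusted p = 0.0277), and its call ended without any 1 of 8 weeks arrays 3 to 6 or 50 weeks arrays 1, 2, 4 and 5 (adjusted p up to 0.0637).

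**Figure D4:**
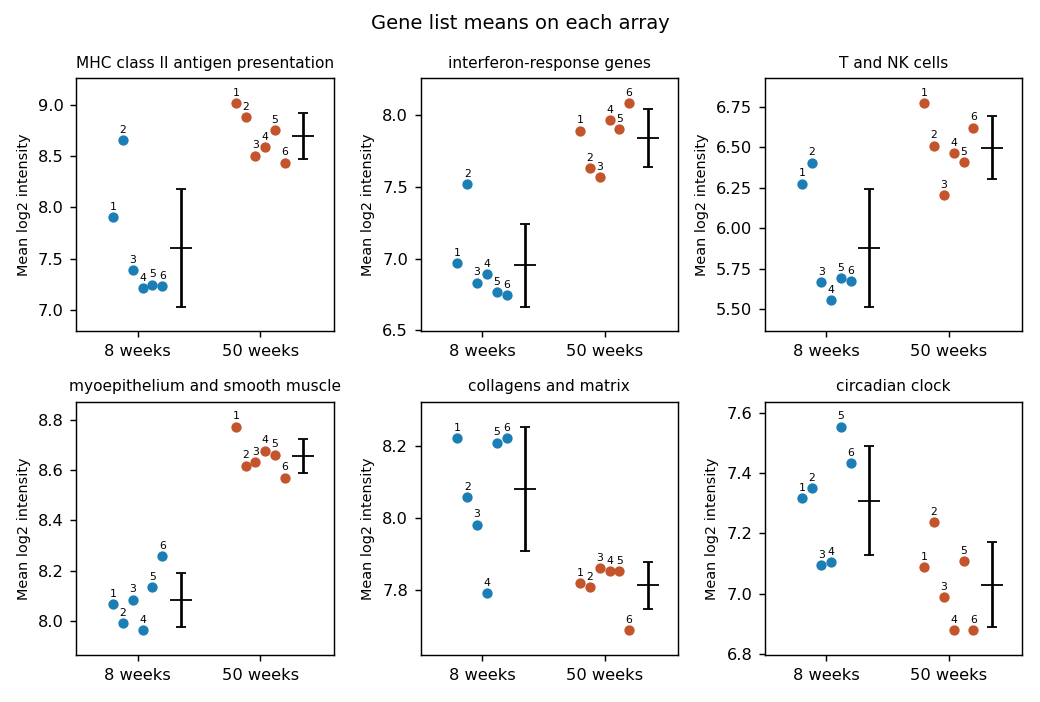
Each point is the mean log2 intensity of a gene list on 1 numbered array at 8 or 50 weeks, and black bars give the mean ± SD of 6 arrays. The interferon and myoepithelium lists lie above every young array on 6 of 6 old arrays, while collagens and the clock lie lower at 50 weeks; with each array scaled to the same median no list passed.

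Contractile cell genes rose with age. The list of myoepithelium, the contractile cells around acini and ducts, and smooth muscle rose from 8.08 ± 0.11 to 8.66 ± 0.07 (SD, n = 6), a difference of 0.57 ± 0.05 that was above every young array on 6 of 6 old arrays. It passed by its mean (adjusted exact permutation p = 0.0325) and was the only list past the threshold in camera with an estimated correlation (adjusted p = 0.0174). Of 11 members 8 rose, 10 adjusted over the list alone: the smooth muscle actins Actg2 (1.02 ± 0.15) and Acta2 (0.41 ± 0.08, from 0.30 to 0.67 over its probes), the actin-binding Tagln (0.73 ± 0.13) and the basal keratin Krt14 (0.52 ± 0.08). Acta2 lost its call with the mean of its probes (adjusted p = 0.123) and with each array scaled to the same median (0.0643). Without 50 weeks array 1 the adjusted exact permutation p of the list was 0.0531. The list of nerve and Schwann cells, with 4 members measured, of 10 on the array, rose by 0.16 ± 0.05 (adjusted exact permutation p = 0.0325, and adjusted p = 0.298 with an estimated correlation). Its 1 member that rose, over all genes and adjusted over the list alone, was the transcription factor Sox10 (0.37 ± 0.08), and the other 3 did not pass. The list members S100b, Prph and Gap43 were detected on 0 of 6 arrays of each age, so the rise cannot be assigned to nerve. The difference was 0.02 without the detection filter (adjusted exact permutation p = 0.77), and the call ended without 8 weeks array 3, 4 or 5 or 50 weeks array 1 (up to 0.0595) and on the authors' values (0.0835).

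Collagen and matrix genes were lower as a list at 50 weeks. The list of collagens and matrix changed from 8.08 ± 0.17 to 7.81 ± 0.07 (SD, n = 6), by -0.27 ± 0.08 (adjusted exact permutation p = 0.0325; adjusted p = 0.392 with an estimated correlation). Of 20 members 7 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. The fibrillar collagens Col3a1 and Col1a1 changed by -1.13 ± 0.12 and -0.97 ± 0.13, and the collagen-binding Sparc by -0.90 ± 0.11. Elastin, Eln, detected on 3 of 6 old arrays, was at least 1.73-fold lower, and all 4 were below every young array on 6 of 6 old arrays. The member that rose was Lum, the proteoglycan lumican (0.54 ± 0.14), chosen after its values were seen. The list mean was below every young array on 1 of 6, that of 50 weeks array 6 at 7.69. Its call ended without 50 weeks array 1 (0.0531), on the authors' values (0.0974) and without both 8 weeks array 2 and 50 weeks array 6 (0.0767). Matrix turnover differed by 0.13 ± 0.05 (adjusted exact permutation p = 0.068, and 0.0235 without 8 weeks array 1), with 1 of 9 members higher and 2 lower, or 3 and 2 adjusted over the list alone. Mmp2, which degrades type IV collagen, changed by -0.51 ± 0.13 (adjusted p = 0.02), with adjusted p = 0.0692 on the authors' values. The endothelium list differed by -0.13 ± 0.06 (adjusted exact permutation p = 0.068, and 0.0325 without 8 weeks array 3). With each array scaled to the same median it differed by 0.009, or by -0.09 relative to the median change of all genes. Of its 12 members 1 passed over all genes and 0 adjusted over the list alone.

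The lists of the main secretory products of the gland did not pass the test. Granular convoluted tubules, the ducts that secrete kallikreins and growth factors in mice, had a list of 14 genes with means of 14.79 at 8 weeks and 14.76 at 50 weeks (difference -0.03 ± 0.03, adjusted exact permutation p = 0.319). With Amy1 as a covariate that list passed, at -0.05 (adjusted approximate permutation p = 0.0278). Its 1 member that fell, over all genes and adjusted over the list alone, was the tissue kallikrein Klk1 (-0.73 ± 0.09, adjusted p = 0.000177), below every young array on 6 of 6 old arrays. Klk1b5 differed by 0.15 ± 0.07 and did not pass (adjusted p = 0.171). These probes lie near the top of the scale, where differences are compressed, and may not tell the kallikreins apart. The list of seromucous acinar products differed by -0.05 ± 0.19 (adjusted exact permutation p = 0.849), with 1 of 11 members higher and 1 lower, and the same counts adjusted over the list alone. Bhlha15, a transcription factor of secretory cells, differed by 0.41 ± 0.11 (adjusted p = 0.0309) and the secreted carbonic anhydrase Car6 by -0.48 ± 0.14 (adjusted p = 0.0399). Both lost their calls without any 1 of 8 weeks arrays 1, 3 and 4 or 50 weeks arrays 1 to 5, and Car6 also without 8 weeks array 5, at adjusted p up to 0.067 and 0.0885. The median changes of the members of both lists, 0.03 and 0.09, had the opposite sign to the mean differences. With each array scaled to the same median the differences were 0.04 and 0.05, or -0.06 and -0.05 relative to the median change of all genes.

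The lists of duct epithelium and of fluid and ion secretion were lower at 50 weeks. The duct epithelium list changed by -0.14 ± 0.06 (adjusted exact permutation p = 0.0497; adjusted p = 0.438 with an estimated correlation), with 3 of 14 members lower and 2 higher, and the same counts adjusted over the list alone. Ascl3, a transcription factor of duct cells, changed by -0.85 ± 0.14 (adjusted p = 0.00188), below every young array on 6 of 6 old arrays. The epithelial sodium channel subunits Scnn1b and Scnn1g changed by -0.39 ± 0.09 and -0.47 ± 0.12, with adjusted p = 0.428 and 0.231 when each array was scaled to the same median. The members that rose were the chloride channel Cftr (0.60 ± 0.17, adjusted p = 0.0332) and the receptor Kit (0.40 ± 0.12, adjusted p = 0.0427), the latter chosen after its values were seen. The call of Cftr ended without any 1 of 8 weeks arrays 1, 2, 4 and 5 or 50 weeks arrays 3, 4 and 5 (adjusted p up to 0.0718). The list of fluid and ion secretion changed by -0.14 ± 0.04 (adjusted exact permutation p = 0.0325; adjusted p = 0.438 with an estimated correlation). Of 13 members 3 fell and 0 rose, and adjusted over the list alone 4 fell and 2 rose. The bicarbonate cotransporter Slc4a4 changed by -0.77 ± 0.16 and the carbonic anhydrase Car2 by -0.96 ± 0.20. The duct call ended without any 1 of 10 arrays (all but 8 weeks arrays 2 and 4, up to 0.106) on the authors' values (0.266), without the detection filter (0.0571) and with the mean of all probes (0.0573). The fluid call ended without 8 weeks arrays 3, 4, 5 or 6 or 50 weeks arrays 1 or 2 (up to 0.0649), without background correction (-0.08, 0.0812), with the strict filter (-0.08, 0.207) and on the authors' values (-0.06, 0.263).

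Amylase, the digestive enzyme most abundant in the parotid gland, varied between samples of both ages. Amy1, chosen after its values were seen, ran from 8.14 to 14.1 at 8 weeks and from 7.73 to 13.8 at 50 weeks. With the arrays taken as independent it differed by -1.16 ± 1.27 between ages (adjusted p = 0.613). Its values on equal-numbered arrays, with the mean of each age removed, correlated at r = 0.927. It was lower at 50 weeks in 6 of 6 numbers, and a replicate block made the same difference pass (adjusted p = 0.0446). With the mean of each age removed, Prpmp5 (r = 0.96, rho = 0.944), Prb1 (r = 0.935, rho = 0.965), both proline-rich protein genes, and Bpifa2, the parotid secretory protein (r = 0.902, rho = 0.825), followed Amy1 over the 12 arrays. With the 12 arrays taken as independent, their permutation p values for r were 1e-05, the smallest possible, 6e-05 and 0.00036, and for rho 0.00024, 7e-05 and 0.0024. Adjusted over 8 correlations the values for r were 8e-05, 0.00024 and 0.00096, and for rho 0.00096, 0.00056 and 0.0064. Without the 2 samples farthest from the median of Amy1, r was 0.957, 0.901 and 0.864. Smgc, a sublingual and neonatal submandibular mucin, had r = 0.129 and rho = 0.0839 (permutation p = 0.711 and 0.806, adjusted 0.848 and 0.806). Dcpp1 had r = 0.67 and rho = 0.727 (permutation p = 0.0246 and 0.013, adjusted 0.0492 and 0.0261), but r = 0.343 without the 2 farthest samples. It ran only from 14.1 to 14.8, and its rho without those samples was not computed. Whether its relation rests on them was therefore not determined. Dcpp2, Dcpp3 and Pip lay near the top of the scale (15 to 15.2, 14.7 to 14.9 and 14.5 to 15), where a relation could not be seen. The list of sublingual or parotid products differed by -0.21 ± 0.52 between ages (adjusted exact permutation p = 0.774), with 0 of 9 members changed over all genes or adjusted over the list alone. The seromucous acinar list was also lowest on arrays 3 and 5 of each age. It stood at 10.17 and 10.41 at 8 weeks and 10.12 and 10.14 at 50 weeks, against at least 10.43 on the other arrays. Its relation to Amy1 was not tested.

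**Figure D5:**
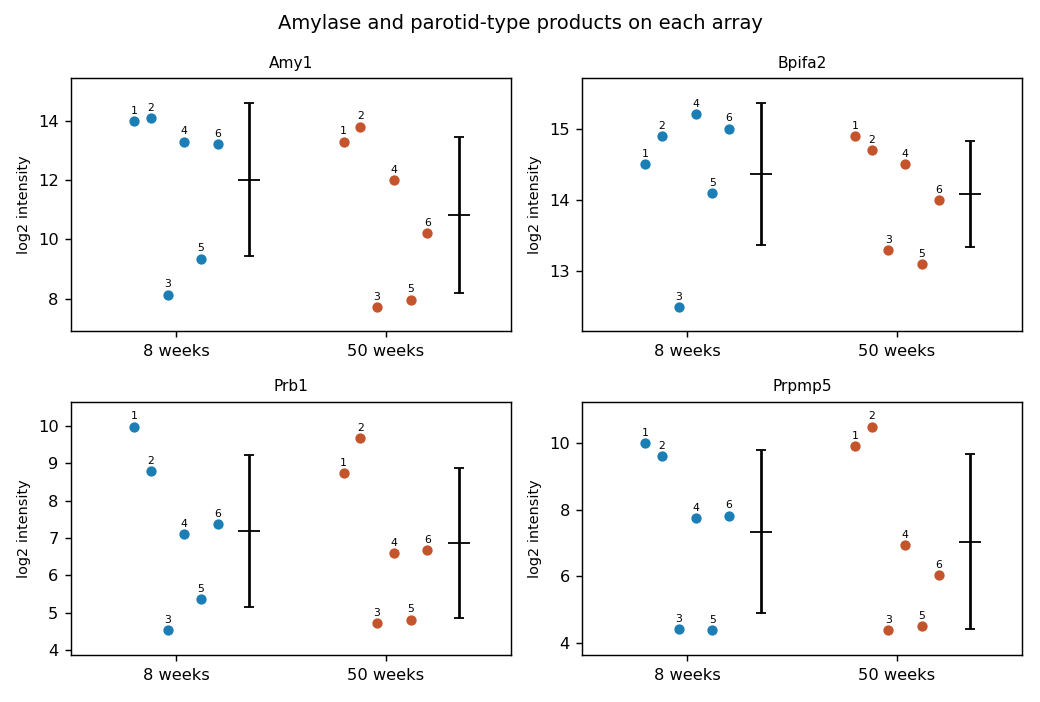
Each point is the log2 intensity of Amy1, Bpifa2, Prb1 or Prpmp5 on 1 numbered array at 8 or 50 weeks, and black bars give the mean ± SD of 6 arrays. Amy1 runs from 8.14 to 14.1 at 8 weeks and from 7.73 to 13.8 at 50 weeks, and arrays 3 and 5 of each age are the lowest of that age for all 4 genes.

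Chaperones of the endoplasmic reticulum were higher as a list. That list, which also holds stress genes, rose by 0.27 ± 0.06, above every young array on 5 of 6 old arrays (adjusted exact permutation p = 0.0325, and adjusted p = 0.203 with an estimated correlation). Of 21 members 7 rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell. Sdf2l1 rose by 1.04 ± 0.14, Creld2 by 0.91 ± 0.11, the disulfide isomerase Pdia6 by 0.77 ± 0.09 (0.29 on another probe) and Dnajc3 by 0.45 ± 0.08, each on 6 of 6 old arrays. The member that fell was the transcription factor Atf4 (-0.44 ± 0.11, -0.13 on another probe), chosen after its values were seen. The list of senescence and secreted inflammation rose by 0.25 ± 0.06 (adjusted exact permutation p = 0.0325; adjusted p = 0.298 with an estimated correlation). Of 11 members measured, of 18 on the array, 3 rose, and adjusted over the list alone 4 rose and 1 fell. The 3 were the insulin-like growth factor binding proteins Igfbp2 (1.33 ± 0.12, adjusted p = 1.71e-05) and Igfbp5 (0.91 ± 0.12) and the adhesion molecule Icam1 (0.64 ± 0.12). The median change of the members was 0.09. Cdkn2a, Il6, Il1a, Tnf and Csf2 were detected on 0 of 6 arrays of each age, and Il1b on 0 of 6 young and 4 of 6 old arrays. The rise therefore cannot be assigned to senescence. Without 50 weeks array 1 the adjusted exact permutation p of both lists was 0.0531.

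Antioxidant enzymes were lower as a list, by -0.19 ± 0.07, below every young array on 5 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.382 with an estimated correlation). Of 22 members 2 fell and 1 rose, and the same counts held adjusted over the list alone. The mitochondrial superoxide dismutase Sod2 changed by -0.34 ± 0.07 and the glutathione transferase Gstp1 by 0.35 ± 0.08 (0.11 on another probe). The list call ended without any 1 of 50 weeks arrays 1 to 5 (up to 0.0852) and on the authors' values (0.0974). With each array scaled to the same median Sod2 and Gstp1 had adjusted p = 0.486 and 0.0994. Oxidative phosphorylation differed by -0.09 ± 0.04 (adjusted exact permutation p = 0.0797, 0.0418 without 50 weeks array 6 and 0.0256 without both it and 8 weeks array 2). With each array scaled to the same median the list differed by 0.03, or by -0.07 relative to the median change of all genes. Of its 35 members 2 were lower over all genes and 0 adjusted over the list alone.

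Clock genes differed in opposite directions. The clock list changed by -0.28 ± 0.09, below every young array on 4 of 6 old arrays (adjusted exact permutation p = 0.0325; adjusted p = 0.408 with an estimated correlation). Of 11 members 4 fell and 1 rose, and adjusted over the list alone 5 fell and 3 rose. Per1, a repressor of the clock, changed by -0.69 ± 0.10 and the output factors Dbp and Tef by -1.70 ± 0.27 and -0.92 ± 0.19. Arntl, the activator whose level runs opposite to theirs over the day, rose by 0.81 ± 0.21 (adjusted p = 0.0233), and lost its call without 8 weeks array 6 or 50 weeks array 4 (adjusted p up to 0.052). The list call ended without any 1 of 8 weeks arrays 2, 5 and 6 or 50 weeks arrays 1, 3, 4 and 6 (up to 0.0702) and without both 8 weeks array 2 and 50 weeks array 6 (-0.24, 0.104). The list difference was -0.16 without background correction, -0.14 on the authors' values and -0.18 with the strict filter. Per1 had adjusted p = 0.118 with each array scaled to the same median.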

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

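The tests of a lower share of epithelium, of parotid or sublingual tissue, of parotid tissue and of array scaling were chosen only after the result was seen. In 35 of 351 groups of 6 arrays, 1 array stood far from the others, by a gap to its nearest neighbour whose share of the range of the group was above Dixon's 95% critical value. Chance gives about 1 in 20 such groups, or 17.6. Of the 35, 18 came from 50 weeks array 6 and 10 from 8 weeks array 2.

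On 50 weeks array 6 the gap was 0.909 of the range for the mean correlation with its own age (r = 0.949 against 0.979) and 0.919 for the second principal component. The array was low for the collagen list (0.706), Bhlha15 (0.694), Creb3l1 (0.838), Car2 (0.791), C4a (0.724), Pmp22 (0.768), Klf4 (0.72), Uty (0.661) and Gapdh (0.659). It was high for the lists of red blood cells (0.714), oxidative phosphorylation (0.73) and antioxidant enzymes (0.635), and for Actg2 (0.637), Tpsb2 (0.686), Scd1 (0.747) and Ndufb5 (0.647). On this array 94 genes lay over 2-fold above the mean of the other 5 arrays of its age and 457 below it. On 8 weeks array 2 those counts were 150 and 15, and on every other array they were at most 49 and 37.

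On 8 weeks array 2 the gap was upward for the MHC class I list (0.689) and the interferon list (0.712). It was upward too for Cxcl9 (0.657), Gbp2 (0.886), Mpeg1 (0.676), H2-Eb1 (0.655), H2-DMa (0.711), Psmb9 (0.704), B2m (0.772) and the muscle actin Acta1 (0.759). The first principal component (0.794) and the macrophage list (0.71) were high on 50 weeks array 1. Krt14 was high on 8 weeks array 6 (0.644), Igfbp5 on 50 weeks array 4 (0.678) and Hsph1 on 8 weeks array 5 (0.783). Klf4 was low on 8 weeks array 4 (0.755) and Pdia6 on 50 weeks array 5 (0.82).

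Immune cell transcripts were higher at 50 weeks, and lymph nodes lie against this gland, so node tissue could have been carried into the old samples. For the old samples as a group, the mean rise of 7 node genes minus that of the T and NK cell list was -0.723 (95% bootstrap interval -0.932 to -0.491). Of the 7 only Ccl21a and Ccl19 were detected on at least 6 arrays, with -0.697 (-1 to -0.363) for these 2 alone. The others were undetected on most arrays and could show little rise. The values of Ccl21a and Ccl19 argue against node tissue as the source of the rise of the whole group. The node gene Glycam1 was highest on 8 weeks arrays 1 and 2, at 8.15 and 6.15, against at most 5.18 elsewhere. Ccl21a stood at 8.94 and 8.28 on the same arrays, against at most 7.66 on the other young arrays. Among old arrays, 50 weeks array 2 had the highest Ccl21a (8.5 against at most 7.54) and the highest B and plasma cell list (7.18). Node tissue in single samples of either age is therefore not excluded. In 8 weeks arrays 1 and 2 it would raise the young means of the node genes and of the immune cell lists, and so lower their rise. A lower share of epithelium, with expression per cell unchanged, would raise the transcripts of every other cell type. The collagen list changed by -0.268 (-0.395 to -0.127) and the list of myoepithelium and smooth muscle by 0.57 (0.474 to 0.662). The collagen value argues against a lower share of epithelium as the only change. A lower share together with lower collagen expression per cell is not excluded. Immune cells or an interferon response within the gland at 50 weeks stay open as a hypothesis, which these arrays did not test.

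Amylase differed by up to 6.36 log2 units between samples, in both ages. Scaling left after normalisation would move all genes, but the range of the housekeeping list was 0.122, a ratio of 0.0191 to the range of Amy1. The normalisation itself evens out scaling, so this range says nothing of scaling before it. Parotid tissue in some samples is a candidate explanation, since Bpifa2, Prb1 and Prpmp5 followed Amy1 with a median r of 0.935. For parotid or sublingual tissue as a whole the median r of 8 genes, 0.4, did not decide, since Dcpp2, Dcpp3 and Pip lie near the top of the scale. Amy1 followed the array number across the ages (r = 0.927 between equal-numbered arrays). What equal numbers share is not given in the sources used here. A difference between mice in what the gland itself expresses stays open, and no biological explanation was tested.

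Clock output genes were lower at 50 weeks. A different time of day at dissection is a candidate explanation: the output genes changed by -0.772 (95% bootstrap interval -1.14 to -0.399) while the mean of Arntl, Npas2 and Clock differed by 0.466 (0.24 to 0.69), a difference of -1.24 (-1.8 to -0.685). Of the output genes Dbp, Tef, Per1 and Nr1d2 passed, while Per2 (-0.78, adjusted p = 0.0919) and Nr1d1 (-0.04, 0.951) did not, and of the opposite set Arntl passed, while Npas2 (0.60, 0.0508) and Clock (-0.01, 0.94) did not. The time of dissection is not given in the sources used here, and a clock shifted by age stays open and was not tested.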

How the results depend on the processing

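The settings with Amy1 or the adipocyte list as a covariate, without 8 weeks array 2 and 50 weeks array 6, and with whole numbers permuted, were chosen only after the data were seen. Unless stated, the cause was not tested. Of 94 named genes past the threshold, 61 passed in every setting that tested them and 0 reversed, while 19 of the others gained a call and 3 changed sign. Of 17 lists past the threshold, 0 passed in every setting and 0 reversed; 7 of the others gained a call in some setting and 8 changed sign. With median scaling 393 genes changed (320 higher, 73 lower) and 0 lists passed. On the authors' values 348 genes were lower, 23 changed at least 2-fold and 11 lists passed (10 higher, 1 lower, against 11 and 6). Lower lists were 2 with Amy1 as a covariate and 3 without 8 weeks array 2 and 50 weeks array 6. Array weights gave 2593 changed genes (1155 higher, 1438 lower), and leaving out 8 weeks array 2 and 50 weeks array 6 gave 2508 (1109 and 1399), with 148 at least 2-fold. The 2-fold count of 97 was 24 without background correction and 41 with an offset of 50, which both compress dim genes by construction, and 48 with the strict filter, which tested fewer genes (6637). The replicate block gave 911 changed genes (501 higher, 410 lower); 10 named genes lost a call and 5 gained one: Cd79b (adjusted p = 0.00888), Egr1 (0.00708), Cfb (0.0345), Cfp (0.0389) and C4a (0.0438). It gave 0 lists, with 13 lists at the smallest p it can give, 0.0312 (adjusted 0.0721). Deviations of equal-numbered arrays correlated at r = 0.25, 0.247, 0.298, 0.165, 0.105 and -0.00923, and not every array correlated best with its own number. For Amy1 they correlated at r = 0.927, it was lower at 50 weeks in 6 of 6 numbers, and the replicate block gave -1.16 (adjusted p = 0.0446). With whole numbers permuted, Prpmp5, Prb1 and Bpifa2 followed Amy1 with adjusted p = 0.0111, 0.0185 and 0.0111, and Dcpp1 did not (0.194). Leaving out 1 array gave 792 (without 50 weeks array 1) to 2317 changed genes (without 50 weeks array 6), 412 to 1047 higher, 380 to 1270 lower, and 0 (without 50 weeks array 1) to 18 lists, of which 0 to 6 lower. In the settings not named, the counts of changed, higher, lower and 2-fold genes and of lists lay within 1.5 times the reported ones. Signal over background limits the dim genes, for which the log2 changes depend on the offset. A block for the slide was not run because the slide is not given in the sources used here, and a covariate for sex-linked transcripts was not run because Eif2s3y and Kdm5d were detected on 6 of 6 arrays of each age, and Xist on 0 of 6 young and 1 of 6 old arrays.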

Other observations

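Gal, Cck, B4galnt2, St6galnac2, Aldh1a3, Hpgd and Slc40a1 were chosen after their values were seen; the tests by other splits of the arrays were written before. The neuropeptide genes Gal (galanin) and Cck (cholecystokinin) rose 3.04-fold and 2.33-fold, above every young array on 6 of 6 old arrays (adjusted p = 0.000476 and 0.000156). B4galnt2 and St6galnac2, which add sugars to glycans, rose by 1.72 ± 0.13 and 1.70 ± 0.21, the latter by 0.18 on another probe. Aldh1a3, which makes retinoic acid, changed by -1.11 ± 0.15, Hpgd, which inactivates prostaglandins, by -1.01 ± 0.11, and the iron exporter Slc40a1 by -1.13 ± 0.12.

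The lists of other cell types and states did not pass, apart from the sex-linked list. Cell cycle genes differed by 0.15 ± 0.07 (adjusted exact permutation p = 0.0903), with 2 of 12 members higher and 1 lower, and the same counts adjusted over the list alone. They passed on the authors' values (0.07, adjusted exact permutation p = 0.0472). They also passed with the adipocyte list as a covariate (0.18, adjusted approximate permutation p = 0.0469). The replication helicase subunits Mcm5 and Mcm4 rose by 0.75 ± 0.14 and 0.39 ± 0.09, Mcm4 with adjusted p = 0.0781 under median scaling. Heat shock genes differed by -0.11 ± 0.05 (adjusted exact permutation p = 0.068) and passed without 8 weeks array 1 or 3 or 50 weeks array 6 (down to 0.046). In that list 2 of 13 members were lower, also adjusted over the list alone: Hspa1a (-0.42 ± 0.08) and Hspa1b (-0.50 ± 0.11), with adjusted p = 0.389 and 0.17 under median scaling. Immediate early genes differed by 0.13 ± 0.14 (adjusted exact permutation p = 0.447), with 0 of 16 changed either way of adjusting. Egr1 differed by 0.81 ± 0.29 and did not pass (adjusted p = 0.0781), but passed without 8 weeks array 2 (adjusted p = 0.0202).

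The adipocyte list differed by -0.48 ± 0.53 (adjusted exact permutation p = 0.5), with 1 of 6 members higher over all genes and adjusted over the list alone, and its SD at 8 weeks was 1.24. Red blood cell genes differed by 0.05 ± 0.20 (0.849), with 0 of 3 changed either way. Housekeeping genes differed by 0.00121 ± 0.0197 (adjusted exact permutation p = 0.952), against a median of -0.02 over the members. Their difference was 0.02 relative to the median change of all genes under median scaling, and -0.05 with the mean of all probes. Gusb was the 1 of 10 that was higher over all genes and adjusted over the list alone (0.41 ± 0.08, 0.16 on another probe). The 3 Y-linked genes Eif2s3y, Kdm5d and Uty were lower as a list by -0.20 ± 0.08 (adjusted exact permutation p = 0.0325; adjusted p = 0.382 with an estimated correlation), with 0 members changed either way. Without 50 weeks array 6 that difference was -0.13, and the call ended without any 1 of 8 weeks arrays 2 to 6 or 50 weeks array 1 (up to 0.0727), on the authors' values (-0.09, 0.166) and without the detection filter (-0.09, 0.231). Lists of mast cells, lymph node stroma and skeletal muscle had 1 measured member each and were not tested. Tpsb2 differed by -0.16, Lyve1, detected on 3 of 6 old arrays, by a fitted -0.37 and Acta1 by -0.65. None of the 3 passed (adjusted p = 0.618, 0.291 and 0.421). With low values raised to the floor of their array, the fold of Lyve1 was 1.33 against a fitted 1.30, so it is not a bound.

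In 100 splits of the 12 arrays into groups of 6, the real one included, 1 split, that by age, gave as many as 1171 changed genes, against at most 279 in the others. Chance is therefore an unlikely source of that count, if the 12 arrays are independent. The 100 splits cannot give a share below 1 in 100. The same held for genes higher (1 split; 596 against at most 181), lower (1 split; 575 against at most 181) and changed at least 2-fold (1 split; 97 against at most 28). For the 14 lists that passed in camera with the preset correlation, 8 of 100 splits gave as many, with up to 16, so chance cannot be excluded for that count.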
